A study of Rattus norvegicus with 6 samples.

How the data were processed

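Gene expression in whole adrenal gland was measured on 6 single-colour Affymetrix RG-U34A arrays, 3 of SHR and 3 of WKY. Each sample was placed in its strain and given its replicate number from its title. Arrays of this kind read labelled RNA with short oligonucleotides grouped into probe sets, and no probe-level file was used here. The authors deposited 1 intensity per probe set and array on a linear scale, with no value below 0. The expression algorithm, its version and the scaling step are not given in the sources used here. The deposited values had been scaled, since the mean after trimming 2% at each end was 2504 in every array. A settings file per array, written by the instrument software and deposited by the authors (other values: chip lot, station, module and order of runs), showed 1 chip lot and 1 fluidics station, and 2 hybridization runs set apart by a gap of over 60 minutes. The first run held SHR replicate 1 and the 3 WKY arrays and the second held SHR replicates 2 and 3. The 4 fluidics modules were shared unevenly, with modules 1 and 2 each holding arrays of both strains.

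Probe sets were named from the array's annotation table, and symbols in the gene lists were brought up to date through the RefSeq gene table of the GRCr8 assembly, which served only for names and for which genes neighbour each other. After 59 control probe sets were left out, 8740 remained, of which 7006 had 1 gene symbol, 308 several and 1426 none. A probe set with several symbols names no single gene, and one with none is unnamed here. Values were used as deposited, because the trimmed means differed by less than 5%, and were taken as log2(intensity + 181.5), the pseudocount being the 20th percentile of all values above 0. A fold change on this scale understates the change of dim probe sets. Probe sets whose mean log2 value over the 6 arrays lay above the 40th percentile were kept, which left 5244 (4312 with 1 symbol, 240 with several, 692 with none). They stood for 3144 genes, and a gene with several kept probe sets, as 881 had, was represented by the brightest.

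Strains were compared with limma 3.58.1 (lmFit, then eBayes with an intensity trend) in R 4.3.3, with statmod 1.5.0, over all 6 arrays with no covariate, as SHR minus WKY. P-values were adjusted by the method of Benjamini and Hochberg over the tested probe sets, with a threshold of 0.05, and limma's tests were two-sided. Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, with 1 probe set per gene, all 3144 genes as background, and adjustment over the 25 of 27 lists with at least 5 measured members. With an estimated correlation 0 of the 3 calls held, although 1 list, the matrix markers, kept an unadjusted p under 0.05 there. The rotation test fry, which asks whether a list's genes move one way on balance and compares them with no others, was run beside it. Members were also adjusted over the list alone. The lists covered catecholamine synthesis, chromaffin granule proteins, exocytosis, steroid synthesis, cholesterol, the renin-angiotensin-aldosterone system, vasoactive peptides, cholinergic and calcium signalling, antioxidant enzymes, oxidative phosphorylation, glycolysis and the tricarboxylic acid cycle, fatty acid oxidation, protein folding, immediate early genes, antigen presentation and the cell cycle. They also covered markers of leukocytes, fibroblasts and capsule matrix, endothelium, smooth muscle, adipocytes, nerve and Schwann cells, skeletal muscle, kidney, liver and plasma proteins and red blood cells, and 6 genes described elsewhere as differing between hypertensive and normotensive strains.

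The lists, tests, filter, pseudocount rule and alternatives were fixed before the data were examined, apart from the first run taken alone, which was added later. So was the rule for the genes named: the 12 largest rises and 12 largest falls among genes with 1 symbol that passed with no overlap between strains, up to 4 members of smallest p from each list, and a fixed set of adrenal and strain genes named whatever their values, some of which are not reported here. Genes outside this rule are said to have been chosen after their values were seen. The alternatives were quantile normalization, scaling to a common median, pseudocounts of 1 and of 4 times the main one, no filter, a filter at the 60th percentile, eBayes without a trend or made robust, the replicate number, the run or the module as a block, each array left out in turn, the mean of a gene's probe sets, and the other set tests.

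The steps were tested on simulated data, 10 tables of 5244 probe sets with the spread of the real arrays and 200 changed probe sets each. For the comparison of SHR with WKY, 5.67% of probe sets changed by a log2 of 0.5 were called, 45.9% at 1 and 87.1% at 2, and 4.31% of the calls were false. A list shifted by 0.5 was called in 10 of 10 tables, and 1 call was made over all tables among the 24 unshifted lists of each. Noise was drawn independently for each probe set, so the genes of a simulated list were uncorrelated. In the real lists the estimated correlation reached 0.41 (adipocyte markers) and was 0.18 for antigen presentation. The simulation therefore does not show how the list test behaves with correlated genes. The number of arrays, 3 per strain, limits the precision given here. The 59 control probe sets were tested apart, and limma called 0 of them (smallest adjusted p = 0.922, 1 at an unadjusted p under 0.05).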

Results

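Adrenal glands of 2 inbred rat strains were profiled on 6 oligonucleotide arrays, 3 from the spontaneously hypertensive rat (SHR) and 3 from the Wistar-Kyoto rat (WKY), the normotensive strain usually set beside it. The adrenal gland joins a cortex, which makes aldosterone and corticosterone, to a medulla of chromaffin cells, which make and release catecholamines, and both hormone classes act on blood pressure. Each array (Affymetrix RG-U34A) carried 8799 probe sets, and the deposited table gave 1 intensity per probe set and array. The arrays had been scaled to a common level, with medians from 798.3 (SHR replicate 3) to 899.5 (WKY replicate 3). Over the tested probe sets, log2 intensities correlated at 0.935 to 0.956 between arrays of a strain and at 0.911 to 0.929 between strains, a correlation across probe sets, which are not independent replicates. The hexokinase control, whose ratio of 3' to 5' signal rises as RNA degrades, read 4.21 in SHR replicate 2 and 1.96 to 2.54 in the other arrays, while the GAPDH ratio ran from 0.901 to 1.14. The labels do not say that the 3 samples of a strain came from separate animals, so p-values measure only the spread between these samples, which may be technical.

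The comparison asked which transcripts differed between the SHR and the WKY adrenal gland. The largest rise in SHR among genes with a probe set of their own was in Akr1c3, an aldo-keto reductase of a family that acts on steroids, at 33807 ± 11287 in SHR against 2220 ± 967 in WKY (mean intensity ± SD, n = 3 each), a 14.4-fold difference on the log scale. Akr1c14, the 3-alpha-hydroxysteroid dehydrogenase of the same family, also rose, at 4576 ± 900 against 1309 ± 584. Jund, a subunit of the AP-1 transcription factor, rose from 152 ± 49.4, a mean below the pseudocount of 181.5, to 1895 ± 119. Scp2, which carries sterols and other lipids within the cell, rose from 2328 ± 49.8 to 7356 ± 344, and Idh1, the cytosolic NADP-dependent isocitrate dehydrogenase, rose from 21385 ± 822 to 57582 ± 5232. On the log2(intensity + pseudocount) scale used from here on, the changes were 3.85 ± 0.32 (SE) for Akr1c3, 1.73 ± 0.29 for Akr1c14, 2.65 ± 0.23 for Jund, 1.59 ± 0.13 for Scp2 and 1.42 ± 0.11 for Idh1, with limma adjusted p of 0.00104, 0.0273, 0.00135, 0.00104 and 0.000708.

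The 12 largest rises were ranked by the brightest tested probe set of each gene. Called probe sets that were not their gene's brightest were left out, such as those of Cyp2a3 at 1.88 and Pdyn at 1.79. Of the other 7 genes among the 12, Sfrp4, a secreted Wnt antagonist, rose by 2.37 ± 0.29 (SE, log2, limma adjusted p = 0.00603). Spp1, which encodes osteopontin, rose by 1.94 ± 0.18 (0.00195). Hp, which encodes the haemoglobin-binding protein haptoglobin, rose by 1.78 ± 0.21 (0.00548). Creg1, a secreted glycoprotein, rose by 1.62 ± 0.21 (0.00880), and Acta2, the smooth muscle actin, by 1.34 ± 0.15 (0.00491). The other 2 Acta2 probe sets did not pass, at 0.61 and 0.73, and the tested ones shared with Actc1 were at 0.08 and -0.006. The others were Cwc25, a splicing factor, at 1.74 ± 0.33 (0.0455) and Ppp1r16b, a regulatory subunit of protein phosphatase 1, at 1.69 ± 0.28 (0.0275). In each of the 12 genes the 3 SHR arrays lay above the 3 WKY arrays, which the rule for naming them required.

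Ranked in the same way, the 12 largest falls in SHR held collagens, class II antigen presentation genes, a fat-derived protease and an enzyme of noradrenaline synthesis. Called probe sets left out of this ranking included those of Etfdh at -3.78 and Mmp2 at -1.81. Dbh, which converts dopamine to noradrenaline, fell from 6425 ± 877 in WKY to 2513 ± 67.8 in SHR (mean intensity ± SD, n = 3 each), a log2 change of -1.29 ± 0.15 (SE; limma adjusted p = 0.00548). Cfd, the complement protease adipsin made mainly by fat cells, went from 7471 ± 3580 to 1613 ± 376, and the fibrillar collagen gene Col3a1 from 17447 ± 3940 to 4996 ± 1367. Their log2 changes were -1.999 ± 0.35 (adjusted p = 0.0324) and -1.78 ± 0.25 (0.0130). Medag, a gene linked to fat cell formation, changed by -2.21 ± 0.30 (0.0123), Ddx42, an RNA helicase, by -2.18 ± 0.30 (0.0123), and Arhgap1, which encodes a GTPase-activating protein, by -1.98 ± 0.27 (0.0113). Klkb1, the plasma prekallikrein gene, changed by -1.80, Cd74 by -1.76, the proteoglycan gene Gpc3 by -1.60, S100a10, which encodes an annexin partner, by -1.60, Col1a1 by -1.39 and RT1-Ba by -1.31, with adjusted p from 0.0122 to 0.0429.

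**Figure D1:**
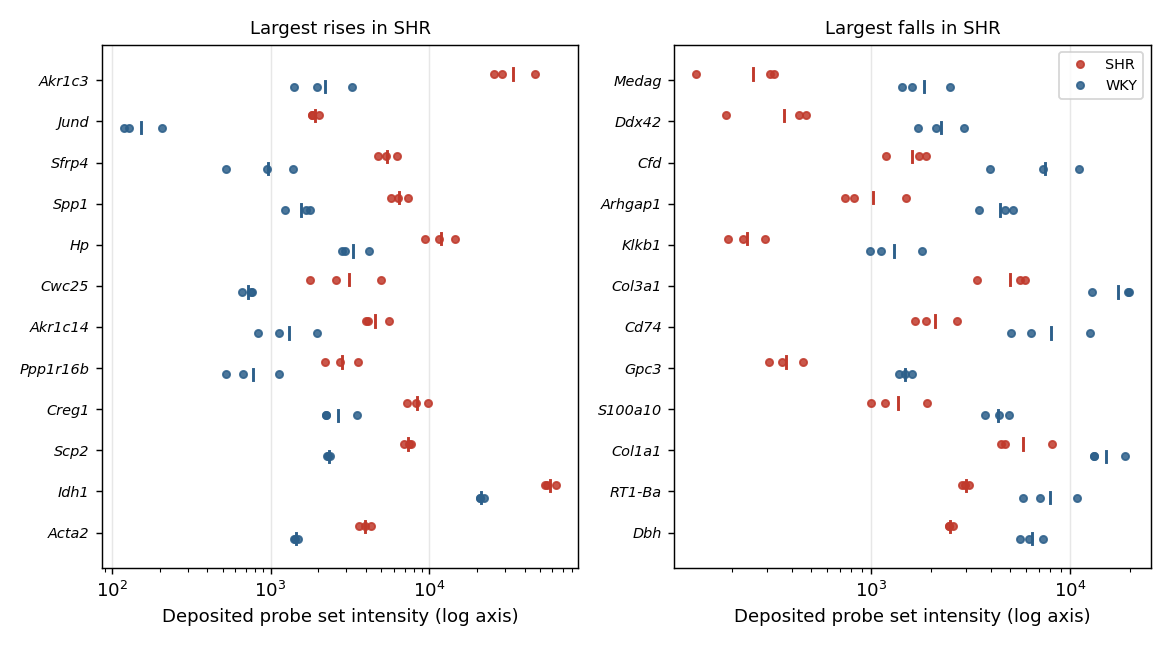
Deposited intensity (log axis) of the 12 genes with the largest rise and the 12 with the largest fall in SHR, with 1 point per array and a bar at the mean of 3 arrays. Genes were ranked by their brightest tested probe set. The SHR and WKY points do not overlap in any of the 24 genes, which the rule for naming them required, and the means of Akr1c3 stand at 33807 against 2220.

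Across the 5244 probe sets tested, limma called 102 (1.95%) at an adjusted p under 0.05, 56 higher and 46 lower in SHR, and 728 passed an unadjusted p of 0.05. Of the 102, 80 differed at least 2-fold and 16 at least 4-fold. The 3 arrays of one strain lay wholly above those of the other in all 102, and in 20.7% of the tested probe sets, where chance gives 10%. By the probe set that stood for each of the 3144 genes, 28 genes rose and 24 fell. The arrays had been hybridized in 2 runs, SHR replicate 1 with the 3 WKY arrays in the first and SHR replicates 2 and 3 in the second. With the run as a block limma called 20 probe sets (11 higher, 9 lower), 16 of them among the 102, and within the first run alone it called 1. The second run held only SHR arrays and gave no value, so both fits set SHR replicate 1 against the WKY arrays. Akr1c3, Jund, Scp2 and Idh1 were the 4 of the 24 genes above that stayed called with the run as a block, with limma adjusted p of 0.0125, 0.0355, 0.0355 and 0.0125. All 102 probe sets kept their sign under that block, where a contrast on 1 SHR array lowers the number of calls by construction. Among the calls lost, Dbh stood at -1.24, Hp at 1.77 and Sfrp4 at 2.35 there, close to the main fit. Others shrank, such as Cwc25 to 1.10 and Col1a1 to -0.86. With each array left out in turn, 9 of the 12 rises and 1 of the 12 falls, Dbh, passed in all 6 fits. The rises that did not were Cwc25, Akr1c14 and Ppp1r16b, and only 3 of the falls passed without WKY replicate 1.

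Wide differences also lay in probe sets that do not name a single gene. Of 7 probe sets for the fatty acid transporter Cd36, 5 name Cd36 and Cd36l1 jointly, all 7 were lower in SHR and 4, all joint, passed the test. The largest of these (rc_AA925752_at) went from 13168 ± 2342 in WKY to 450 ± 129 in SHR (mean intensity ± SD, n = 3 each), a log2 change of -4.41 ± 0.21 (SE; limma adjusted p = 0.000176), and the other 3 changed by -3.60, -2.19 and -1.69. The probe set that stood for Cd36 alone changed by -1.44 ± 0.35 and did not pass (adjusted p = 0.0969). Etfdh, which passes electrons from fatty acid oxidation to ubiquinone, had 1 probe set that fell by 3.78 ± 0.23 (adjusted p = 0.000249), from 2957 ± 390 to 45.8 ± 14.1, and 2 others that did not pass, at 0.14 ± 0.13 and 0.62 ± 0.17. Snurf and Snrpn jointly, which share one imprinted transcript, rose in 2 probe sets, by 1.44 ± 0.17 and 1.00 ± 0.17 (adjusted p = 0.00548 and 0.0302). A probe set shared by Rpl17 and its copies changed by -1.61 ± 0.13 (0.00104), and one shared by the complement genes Cfb and C2 by -0.81 ± 0.14 (0.0275). A further 13 of the 102 are unnamed here, among them M93257_s_at at 3.69 ± 0.33 and M31038_at at 3.09 ± 0.18, both higher, and rc_AI639186_at at -4.12 ± 0.49. With the hybridization run as a block the calls were lost for the Cd36 probe set at -1.69 (adjusted p = 0.172), both probe sets of Snurf and Snrpn (0.0796 and 0.265), the one of Cfb and C2 (0.332) and rc_AI639186_at (0.136). Their log2 changes there were -1.82, 1.52 and 1.00, -0.67 and -3.71. The other 3 called Cd36 probe sets, those of Etfdh and Rpl17, M93257_s_at and M31038_at stayed called. Of the 6 fits without 1 array, that Cd36 probe set passed in 2, the second of Snurf and Snrpn in 1 and the one of Cfb and C2 in 0. These features were chosen after their values were seen, apart from Cd36.

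**Figure D2:**
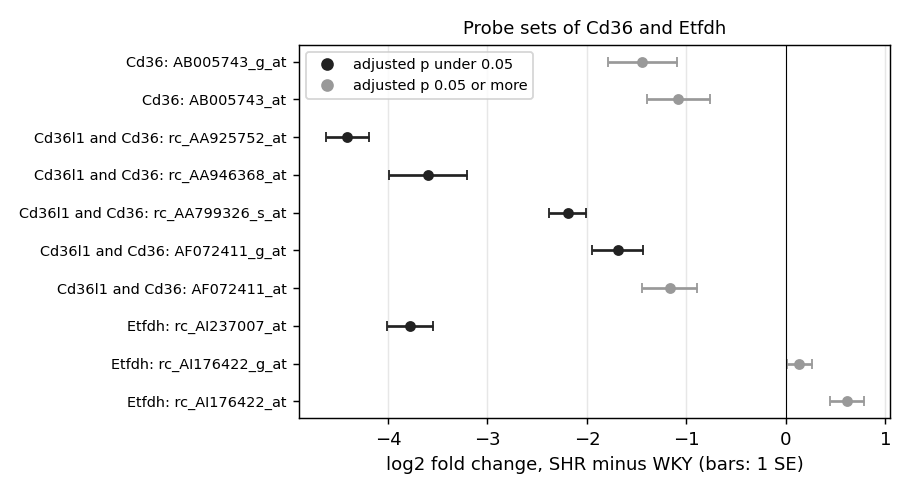
Log2 fold change (SHR minus WKY) of each probe set for Cd36, alone or joined with Cd36l1, and for Etfdh, with bars of 1 standard error and filled black points at an adjusted p under 0.05. All 7 Cd36 probe sets lie below 0, from -4.41 to -1.08, and 1 of 3 Etfdh probe sets does, at -3.78.

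By the probe set that stood for each gene, Dbh was the 1 medulla gene listed that passed. Of 13 measured genes of catecholamine synthesis and metabolism, 0 rose, 1 fell and 12 did not pass, and adjusted over the list alone 2 were lower, Dbh and Pnmt. Pnmt, which converts noradrenaline to adrenaline, stood at 13549 ± 1568 in SHR and 20127 ± 1115 in WKY (-0.57 ± 0.13; limma adjusted p = 0.0764 over all probe sets). Th, the rate-limiting enzyme of the pathway, was at -0.02 ± 0.18 (SE; adjusted p = 0.973) and Ddc, the decarboxylase that acts after it, at 0.14 ± 0.14 (0.712). The vesicular monoamine transporter gene Slc18a1 was at -0.82 (0.191) and Maob, which degrades monoamines, at -0.72 (0.270). Slc18a2, the other vesicular transporter, chosen after its value was seen, was at 0.91 ± 0.38 (0.329). As a set the list had a median of -0.16 and did not pass limma's camera test (adjusted p = 0.147), but passed fry, which compares it with no other genes (down, adjusted p = 0.0372).

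Of 11 chromaffin granule and neuropeptide genes, 0 passed over all probe sets (5 at an unadjusted p under 0.05), while adjusted over the list alone 2 were higher and 1 lower. The higher ones were Cpe, a prohormone-processing carboxypeptidase, at 0.74 ± 0.15, and Pdyn, the dynorphin precursor, at 0.69 ± 0.17, and the lower one was Resp18 at -0.73 ± 0.20. A second Pdyn probe set, which did not stand for the gene, rose by 1.79 ± 0.13 (limma adjusted p = 0.000651, and 0.0294 with the hybridization run as a block). Chgb, a granule protein, was at -0.08 (adjusted p = 0.856), Npy at -0.58 (0.329) and Penk at -0.45 (0.492), and no probe set named Chga alone. The set median was -0.08 and the mean -0.03, while camera's direction was up, with an adjusted p of 0.986. None of 24 genes of regulated exocytosis passed over all probe sets or adjusted over the list alone, and the 3 at an unadjusted p under 0.05 were Napa at 0.37, Vamp2 at 0.34 and Snap25 at -0.70 (median 0.01, mean -0.0004, camera direction up, adjusted p = 0.852). Likewise 0 of 26 genes of cholinergic and calcium signalling passed either way, and 3 did at an unadjusted p under 0.05, with Prkce at 0.74 ± 0.19 (median 0.14, camera adjusted p = 0.147).

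Genes of the cortex gave 1 call. Of 18 measured genes of steroid hormone synthesis, 1 rose, Akr1c14, and 17 did not pass, and adjusted over the list alone 3 were higher, Akr1c14, Inha and Nr0b1. Inha, the inhibin alpha subunit, stood at 0.59 ± 0.13 (limma adjusted p = 0.0732 over all probe sets) and Nr0b1, a nuclear receptor that represses steroidogenic genes, at 0.85 ± 0.22 (0.122). Star, which brings cholesterol into mitochondria, was at 74944 ± 17177 in SHR and 85421 ± 17100 in WKY (mean intensity ± SD, n = 3 each; -0.20 ± 0.19, adjusted p = 0.707), and Cyp11a1, the side-chain cleavage enzyme, at -0.07 (0.859). Cyp21a1 was at -0.56 (0.633) and Cyp11b2, the aldosterone synthase, at 0.24 (0.813), and no probe set named Cyp11b1 alone. One shared by Cyp11b1 and Cyp11b2 was at 55811 ± 21308 in SHR and 98108 ± 26876 in WKY (-0.85 ± 0.31, adjusted p = 0.261). Another, shared by Cyp11b1 and Cyp11b3, was at 0.19 ± 0.11 (0.473). The list's median was 0.19 (camera adjusted p = 0.178), and it passed fry (up, adjusted p = 0.0372). Of 17 genes of cholesterol synthesis and uptake 0 passed either over all probe sets or adjusted over the list alone (2 at an unadjusted p under 0.05), 13 of the 17 had a negative sign, Sqle was at -0.70 ± 0.20 and Scd at -1.12 ± 0.53, and the median was -0.28 (camera adjusted p = 0.128). The list passed, down, with the hybridization run as a block (0.00110), in the first run alone (0.00213) and without SHR replicate 3 (0.0202) or WKY replicate 3 (0.0115). Scarb1, which takes up cholesterol from lipoproteins, was at -0.10 (0.869).

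In the renin-angiotensin-aldosterone system, 0 of 9 measured genes passed over all probe sets (3 at an unadjusted p under 0.05), and adjusted over the list alone 1 was higher, the protease gene Ctsd at 0.56 ± 0.12 (limma adjusted p = 0.0590 over all probe sets). The angiotensin receptor genes were at 0.48 (Agtr1a, adjusted p = 0.233), -0.17 (Agtr1b, 0.691) and 0.07 (Agtr2, 0.956). The precursor Agt was at -0.86 ± 0.43 (0.420), with WKY replicate 1 at an intensity of 3305.5 and WKY replicates 2 and 3 at 1149.1 and 1052.4. The set median was 0.01 (camera adjusted p = 0.560). None of 20 genes of vasoactive peptides, receptors and nitric oxide passed over all probe sets, adjusted over the list alone or at an unadjusted p of 0.05, with Gucy1a1 at -0.41 (median 0.02, camera adjusted p = 0.986).

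**Figure D3:**
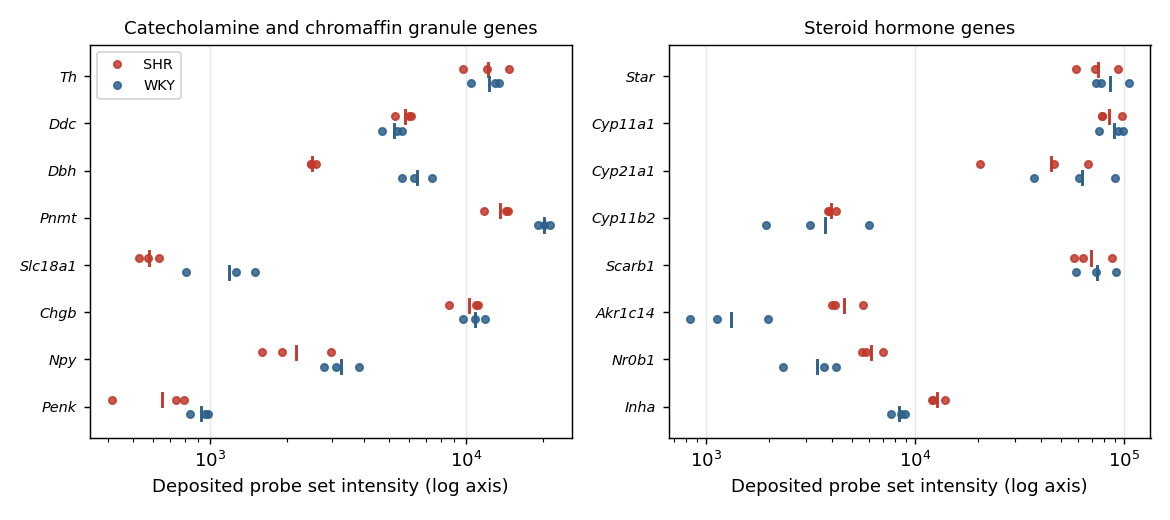
Deposited intensity (log axis) of 8 genes of the medulla and 8 of the cortex, with 1 point per array and a bar at the mean of 3 arrays. Dbh and Akr1c14 passed the test, at 2513 against 6425 and 4576 against 1309 (SHR against WKY), and the others did not.

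Glutathione enzymes and enzymes of central carbon metabolism gave 5 calls by the probe set that stood for each gene, all higher in SHR. Of 33 measured antioxidant and glutathione genes, 2 rose, 0 fell and 31 did not pass, and adjusted over the list alone 4 were higher, Gsta4, Gstt1, Gstm1 and Hmox1. Gsta4 and Gstt1, both glutathione transferases, rose by 1.26 ± 0.21 (limma adjusted p = 0.0271) and 0.79 ± 0.15 (0.0411), and Gstm1, of the same class, was at 0.78 ± 0.16 (0.0608). With the hybridization run as a block neither Gsta4 (0.248) nor Gstt1 (0.366) stayed called, at log2 changes of 1.23 and 0.72. Of the 6 fits without 1 array they passed in 1 and 0. Sod1, also listed and chosen after its values were seen, did not pass by the probe set that stood for it. Another was called higher, at 1.02 (0.99 with the run as a block), and its 2 uncalled ones averaged -0.08. As a set the list passed limma's camera (median 0.07, mean 0.17, adjusted p = 0.0447), but not with an estimated correlation (adjusted p = 0.675 with an estimated correlation), nor under fry (0.165), nor with the hybridization run as a block (0.0897), with the mean shift at 0.21 there and within the first run. Of 25 genes of glycolysis and the tricarboxylic acid cycle, 3 rose, 0 fell and 22 did not pass, with the same 3 adjusted over the list alone. They were Idh1, the malic enzyme gene Me1 at 1.29 ± 0.18 (0.0125), called in 4 of its 5 probe sets, and Pfkp, a phosphofructokinase, at 1.06 ± 0.13 (0.00603). With the run as a block Pfkp (0.135) and that Me1 probe set (0.140) lost their calls, at log2 changes of 1.05 and 1.38. Under that block 2 other Me1 probe sets stayed called (0.0355 and 0.0469). The list's median was -0.10, its mean 0.05 and its camera direction up (adjusted p = 0.894).

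The remaining lists of cell function gave 1 call by the probe set that stood for each gene. Of 22 immediate early genes 1 rose, Jund, and adjusted over the list alone Jund was higher and Klf10 lower, the latter at -0.65 ± 0.16 (limma adjusted p = 0.107 over all probe sets). Jun was at -0.49 ± 0.14 (0.140) by the probe set that stood for it, and 1 of its other 3 fell by 1.37 ± 0.18 (0.00922, and 0.162 with the hybridization run as a block). The set median was 0.19 (camera adjusted p = 0.340). The list passed, up, with the fluidics module (9.12e-06) or the replicate number (0.0470) as a block and without SHR replicate 1 (0.0308). With the hybridization run as a block its direction was down and it did not pass. Oxidative phosphorylation had 33 measured genes, fatty acid oxidation 27, protein folding and heat shock 22 and the cell cycle 15. None of these passed by the probe set that stood for the gene, over all probe sets or adjusted over the list alone. At an unadjusted p under 0.05 the counts were 2, 7, 2 and 1. Their medians were -0.07, 0.15, 0.01 and -0.07 and their camera adjusted p 0.852, 0.147, 0.983 and 0.340. Among the fatty acid oxidation genes, another probe set of Etfdh was called lower, at -3.78. So were 4 probe sets shared by Cd36 and Cd36l1. The oxidative phosphorylation genes of smallest p were Atp5if1 at -0.69 ± 0.19 and Cox7b at -0.39 ± 0.14, the fatty acid oxidation genes beside Cd36 were Decr1 at 0.69 ± 0.18 and Cpt2 at 0.52 ± 0.17, and the chaperone gene Hspa1a was at 1.11 ± 0.32.

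Collagen genes led the cell type lists, with 4 of them lower in SHR. Of 20 measured fibroblast and capsule matrix markers, 0 rose, 5 fell and 15 did not pass by the probe set that stood for each. Adjusted over the list alone 9 were lower. The 5 were the collagen genes Col3a1, Col1a1, Col1a2 (-0.98 ± 0.17, limma adjusted p = 0.0302) and Col5a1 (-0.81 ± 0.14, 0.0302) and the fibronectin gene Fn1 (-0.997 ± 0.19, 0.0481), and the proteoglycan gene Dcn (-1.45 ± 0.33, 0.0786) and the collagen gene Col5a2 (-0.58 ± 0.16, 0.140) were among the 9, with Dcn called lower in 1 of its 4 probe sets (0.413 with the hybridization run as a block, and past the threshold in 1 of the 6 fits without 1 array). The second Col3a1 probe set was at -0.85 and did not pass (limma adjusted p = 0.258). Fn1 was called in 1 of its 3 probe sets and Col1a1 in 3 of its 4, with all of them negative. Mmp2, also listed, did not pass by the probe set that stood for it, at 0.24, while its other was called at -1.81. Fn1, Dcn, Col5a2 and Mmp2 were chosen after their values were seen. With the hybridization run as a block 0 of the 5 stayed called (limma adjusted p from 0.222 for Col3a1 to 0.391 for Fn1). Under that block Col3a1 stood at -1.50, Col1a1 at -0.86, Col1a2 at -0.69, Col5a1 at -0.69 and Fn1 at -0.89. Col5a1 and Fn1 passed in 0 of the 6 fits without 1 array. The list's median was -0.49 (camera adjusted p = 4.43e-05), but the call was lost with an estimated correlation (adjusted p = 0.407 with an estimated correlation). Without a block the mean shift was -0.53, and it was -0.44 both with the hybridization run as a block and within the first run (camera adjusted p = 0.000336 and 0.000467).

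By the probe set that stood for each gene, the 3 antigen presentation genes that passed were all of class II, and all fell. Of 16 measured antigen presentation genes 0 rose, 3 fell and 13 did not pass, and adjusted over the list alone 5 were lower and 1 higher. Cd74, the class II invariant chain, fell from 8007 ± 4037 in WKY to 2096 ± 556 in SHR (mean intensity ± SD, n = 3 each; limma adjusted p = 0.0429), and the class II chain genes RT1-Ba and RT1-Db1 changed by -1.31 ± 0.22 (0.0297) and -1.22 ± 0.23 (0.0403), while RT1-CE12, of class I, was at 0.50 ± 0.11 (0.0711). The other 2 RT1-Ba probe sets were not called, at 0.10 ± 0.19 (0.866) and -0.76 ± 0.27 (0.258). RT1-Bb, another class II chain gene, did not pass by the probe set that stood for it, at -0.26. Its other probe set was called lower, at -2.03, and changed by -1.72 with the hybridization run as a block. That probe set passed in all 6 fits without 1 array. RT1-Bb was chosen after its values were seen. With the hybridization run as a block 0 of the 3 genes that had passed stayed called (limma adjusted p = 0.232 for Cd74, 0.287 for RT1-Ba and 0.343 for RT1-Db1). Their log2 changes there were -2.04, -1.24 and -1.14. The list's median was -0.28 (camera adjusted p = 0.00566), and the call was lost with an estimated correlation (adjusted p = 0.511 with an estimated correlation) and under fry (0.105). The mean shift was -0.47, and -0.49 both with the hybridization run as a block and within the first run (camera adjusted p = 0.00501 and 0.00883). Of 14 leukocyte markers 0 passed over all probe sets or adjusted over the list alone, and 1 at an unadjusted p under 0.05, C1qb, a complement component of macrophages, at -1.02 ± 0.28, and the median was -0.12 (camera adjusted p = 0.534).

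Markers of the remaining cell types that an adrenal sample can hold gave 2 calls. Of 6 smooth muscle markers 1 rose, Acta2, with the same 1 adjusted over the list alone, while Tagln was at 0.14 ± 0.26 and Myh11 at -0.14 ± 0.30 (median 0.06, limma camera adjusted p = 0.366, fry up at 0.0372). Of 8 adipocyte markers 1 fell, Cfd, with the same 1 adjusted over the list alone, and Fabp4, the fat cell lipid-binding protein, was at -1.52 ± 0.52 (adjusted p = 0.235; median -0.36, camera adjusted p = 0.128). WKY replicate 3 had a lower adipocyte mean than any SHR array, and without it the list passed (0.00130) with a mean shift of -0.94 in place of -0.57. It also passed with the module as a block (0.00214) and with the mean of a gene's probe sets (0.0455). None of the 7 endothelial, 7 nerve and Schwann cell, 7 kidney or 8 liver and plasma protein markers passed over all probe sets or adjusted over the list alone, with medians of -0.19, -0.19, -0.25 and -0.10 and camera adjusted p of 0.852, 0.128, 0.986 and 0.560. At an unadjusted p under 0.05 the counts were 0, 2, 2 and 2. The nerve list passed fry (down, adjusted p = 0.0372). The members of smallest p in these lists were Flt1, positive where its list's median was not, at 0.31 ± 0.23, Prph at -1.14 ± 0.32, Aqp1 at 0.45 ± 0.16 and Serpina1 at -1.36 ± 0.41. Of 6 skeletal muscle markers 0 passed over all probe sets and 1, also the only one at an unadjusted p under 0.05, was higher adjusted over the list alone, Myh1 at 1.16 ± 0.29 (median 0.04, camera adjusted p = 0.720). The 4 measured red blood cell markers were too few for the set test, and 0 passed over all probe sets while 2, the same as at an unadjusted p under 0.05, were lower adjusted over the list alone, the haemoglobin genes Hbb at -0.95 ± 0.28 and Hbb-b1 at -0.74 ± 0.19.

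**Figure D4:**
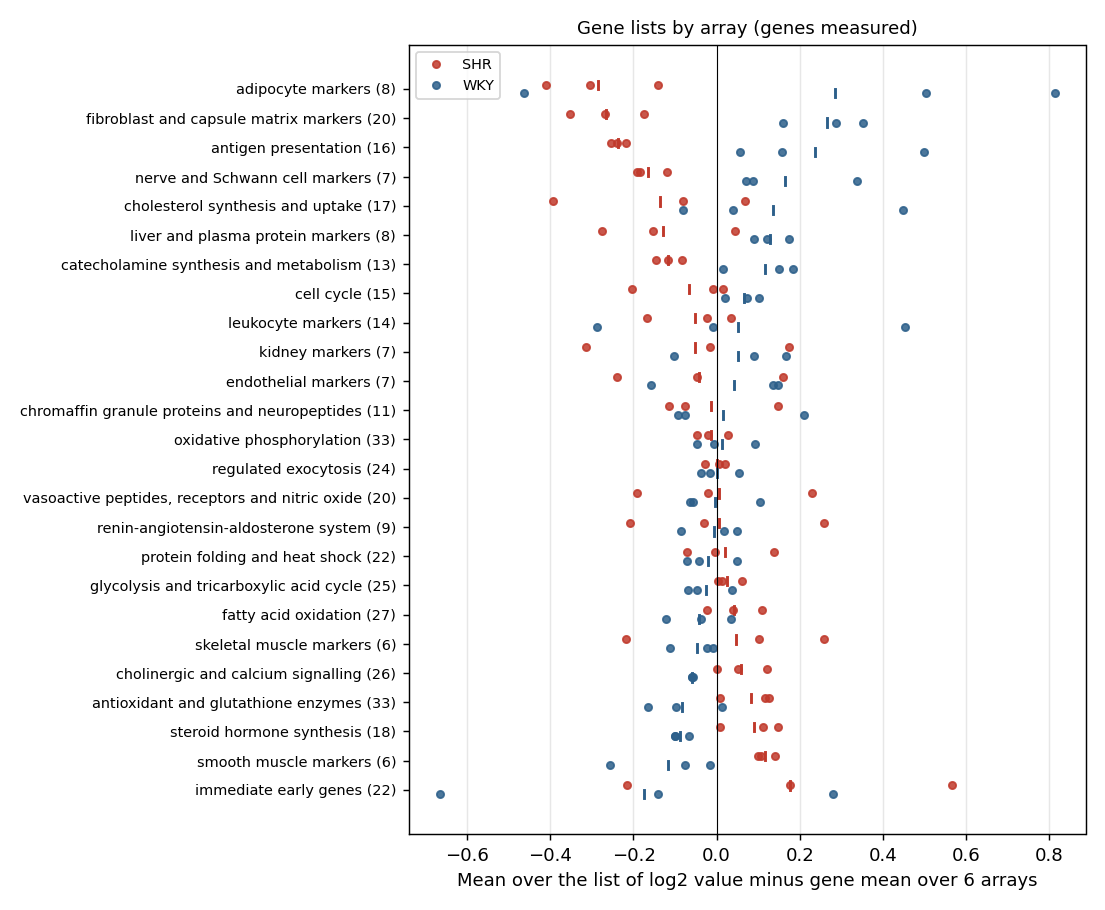
Mean over each gene list of the log2 value minus the gene's mean over the 6 arrays, with 1 point per array and a bar at each strain's mean; the number of genes measured stands in parentheses. The 3 SHR points of the matrix list lie between -0.35 and -0.17 and the 3 WKY points between 0.16 and 0.35.

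A short list of genes described elsewhere as differing between hypertensive and normotensive strains had 4 measured members, too few for the set test. By the probe set that stood for each gene, 0 passed over all probe sets (2 at an unadjusted p under 0.05). Adjusted over the list alone Gstm1 was higher and Cd36 lower. Another 4 probe sets, shared by Cd36 and Cd36l1, were called lower over all probe sets. Ephx2, the soluble epoxide hydrolase gene, was at -0.27 ± 0.21 (limma adjusted p = 0.630) and Srebf1, a regulator of lipid synthesis, at 0.06 ± 0.19 (0.922), while Acsm3 lay under the intensity filter. Probe sets of one gene did not always move together. Of 33 called genes with at least 2 tested probe sets, 22 had all of them on one side of 0, 4 had every one called and 11 had at least 1 of opposite sign, Etfdh, Jun and RT1-Ba among them.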

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

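The first hybridization run taken alone was chosen after the data were seen, and the other alternatives before. All 102 called probe sets kept their sign under both other normalizations and with the hybridization run as a block. Of these, 33 stayed past the threshold in all 6 fits that left out 1 array. Counts of called probe sets (total, higher, lower) stayed within 1.5 times of 102, 56 and 46 under both normalizations, both pseudocounts, both filters and the robust fit, between 83 and 109 in total. Log2 changes of dim genes moved with the pseudocount, from 3.68 (pseudocount of 1) to 1.58 (4 times the main one) for Jund, -2.91 to -1.37 for Medag, -2.70 to -1.44 for Ddx42, -2.43 to -1.06 for Klkb1 and -2.01 to -1.01 for Gpc3, and these 5 stayed called at both. They fell to 60, 31 and 29 without the intensity trend, 46, 28 and 18 with the fluidics module as a block, 20, 11 and 9 with the hybridization run as a block (482 at an unadjusted p under 0.05), and 1, 0 and 1 in the first run alone (438), where the contrast rests on 1 SHR array assumed to vary like the others. Leaving out 1 array gave 38 (without SHR replicate 2) to 59 in total, 22 to 36 higher and 16 to 29 lower, and every array left out moved the total by over 1.5 times, to 53, 38 and 48 without SHR replicates 1, 2 and 3 and 52, 59 and 58 without WKY replicates 1, 2 and 3. Fewer arrays lowered these counts by construction, and so did the run as a block, which sets only SHR replicate 1 against the WKY arrays. The share of higher calls was 54.9%, and it was 65.4% without WKY replicate 1, 49.1% without SHR replicate 1, 48.2% without a filter and 60.8% under scaling to a common median. The replicate numbers share only a number, since residuals of same-numbered arrays correlated at 0.00088, 0.010 and 0.071. With the replicate block 53 probe sets were called, 31 higher and 22 lower.

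Of the 3 list calls, 0 held with an estimated correlation and fry called 5 lists (the matrix list at 0.0318, and the catecholamine, steroid, smooth muscle and nerve lists at 0.0372), and leaving out 1 array gave 2 to 4. The matrix list lost its call only with an estimated correlation (adjusted p = 0.407; 3.12e-05 to 0.000535 with 1 array left out). The antigen presentation list lost it there (0.511) and under fry (0.105; 0.000907 to 0.0277 with 1 array left out). The antioxidant list lost it in 17 of 21 alternatives, with an adjusted p of 0.0819 for the mean of probe sets, 0.675 with an estimated correlation, 0.165 under fry, 0.0719 under quantile normalization, 0.0570 under median scaling, 0.130 with 4 times the pseudocount, 0.0804 without a filter, 0.0588 with the stricter one, 0.0603 with the replicate block, 0.0897 with the run block, 0.143 with the module block, 0.133 in the first run alone and 0.00695 to 0.130 with 1 array left out. The cause of these losses was not tested. Among lists not called, 14 alternatives passed the threshold, 4 of them for cholesterol synthesis (0.00110 with the run as a block), 3 for immediate early genes (9.12e-06 with the module as a block), 3 for adipocyte markers (0.00130 without WKY replicate 3) and 4 under fry. Over 553 comparisons of named called genes 364 stayed past the threshold and 189 did not, and among all 2346 comparisons of named genes 12 uncalled ones passed. The smallest change called was 0.58 on the log2 scale, and whether signal over background sets it was not tested.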

Other observations

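Tests of other cell types, of attached fat, of probe sets within a gene and of other splits were chosen after the results were seen, and so were the genes named in the next paragraphs. Of the called genes not yet described, Ucp2, an inner mitochondrial membrane carrier, fell from 36817 ± 2084 in WKY to 16629 ± 1548 in SHR (mean intensity ± SD, n = 3 each), a log2 change of -1.14 ± 0.11 (SE; limma adjusted p = 0.00269), and both of its probe sets were called. Xdh, the xanthine dehydrogenase that makes uric acid, fell by 1.01 ± 0.16 (0.0254). Aldh1l1, a folate enzyme that yields NADPH, rose by 1.20 ± 0.13 (0.00421), Cyp4f6, a fatty acid and eicosanoid hydroxylase, by 1.32 ± 0.24 (0.0350), and Adh1c, an alcohol dehydrogenase, by 0.90 ± 0.17 (0.0465).

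Among the other calls, Prlr, the prolactin receptor, was among the brighter probe sets and rose from 28854 ± 1922 to 44086 ± 1471 (0.61 ± 0.10; limma adjusted p = 0.0271), with 1 of its 5 probe sets called. Grb14, an adaptor that damps insulin receptor signalling, rose by 1.15 ± 0.22 (0.0483), and Cdh22, a cadherin, by 1.15 ± 0.21 (0.0403). Itga1, a collagen-binding integrin chain, changed by -1.14 ± 0.15 (0.00880), Lgals3, which encodes a galectin, by -1.10 ± 0.16 (0.0140), the cytokine gene Il18 by -1.14 ± 0.19 (0.0297), and Cst3, a protease inhibitor, by -0.77 ± 0.13 (0.0280). None of the 12 genes in these paragraphs stayed called with the hybridization run as a block, where their limma adjusted p ran from 0.0695 (Ucp2) to 0.376 (Cdh22). All kept their sign there, with Ucp2 at -0.99, Aldh1l1 at 1.25, Itga1 at -1.24, Grb14 at 1.39, Xdh at -0.83 and Cdh22 at 1.01. Prlr, Grb14, Adh1c and Cst3 passed in 0 of the 6 fits without 1 array, and Ucp2 and Aldh1l1 in all 6.

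Of the 10 splits of the 6 arrays into 3 and 3, 1, the real one, gave as many as 102 changed probe sets, and the highest other gave 0 (256 at an unadjusted p under 0.05), but 10 splits are too few for a share under 0.05. A difference between the 2 hybridization runs is a candidate explanation, since 2 of the 3 SHR arrays had a run of their own. Of the 53 probe sets called without SHR replicate 1, that array, hybridized with the WKY arrays, lay outside the WKY range on the called side in 52, or 98.1%, where 25% would follow if the 4 arrays of the run were alike and selection on the WKY values is left aside. That share goes against the run as the whole cause, but it rests on 1 array and on probe sets picked with the same WKY values, so a share past the bound of 50% set beforehand does not exclude it. In the 53 probe sets the difference from the WKY arrays in SHR replicate 1 had a median ratio of 0.96 to that in SHR replicates 2 and 3. This too rests on 1 array. With 1 SHR array in the first run, the data do not show how much of each change came from the run and how much from strain. Both stay open.

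Lower matrix genes in SHR were weighed against tissue makeup and the run. A smaller share of all supporting tissue would lower smooth muscle and endothelial genes alike, but the matrix mean (-0.53 ± 0.08 SE, log2) lay below the mean of 13 such genes (0.06 ± 0.11) by -0.59 ± 0.17. With the mean of 8 adipocyte markers as a covariate, to allow for less attached fat, it was -0.46 ± 0.08 (95% interval -0.72 to -0.20), but the interval reached 0 without WKY replicate 3 (-0.59, -1.96 to 0.79) and without SHR replicate 3 (-0.44, -0.92 to 0.033). A run effect would leave SHR replicate 1 among the WKY arrays, and its matrix mean lay -0.44 from theirs (SD of the 3, 0.098), past the bound set beforehand, which 1 array cannot carry. Less attached fat, the run, fewer fibroblasts or a thinner capsule in the dissected SHR samples, and lower matrix expression in SHR may each give this pattern and stay open.

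Lower class II genes were weighed against fewer leukocytes and less fat. The 7 class II genes differed by -0.98 ± 0.24 (SE, log2) and the 14 leukocyte markers by -0.10 ± 0.22, and the difference between them was -0.87 ± 0.07. The class II genes were set apart after falls among them were seen, so part of that gap was built in. It does not decide whether leukocytes of every kind were fewer in SHR. With the fat markers as a covariate the class II difference was -0.83 ± 0.31 (95% interval -1.81 to 0.16, and -2.26 ± 0.68 without WKY replicate 3), so a part played by attached fat cannot be told apart from a strain difference with 6 arrays. A smaller number of antigen-presenting cells in particular, and class II genes that hybridize less well because of strain variants of this polymorphic family, may also contribute and were not tested. Of the 10 splits, 4, the real one included, gave at least 3 lists past the threshold, with 3 in the real one and 5 in the highest other, and 10 splits are too few for a share under 0.05.

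The probe set rc_AI237007_at for Etfdh fell while the mean of the other 2 was 0.38. A strain difference in the sequence or transcript end under that probe set is a candidate explanation that stays open, since these are the values that prompted it. Variants under single probe sets as the whole cause of the calls would leave the uncalled probe sets of called genes without a preferred sign. In 22 of 29 genes, or 75.9%, they shared the sign of the called one (exact two-sided binomial p = 0.00813), and 7 genes had the opposite sign. In Gsta4, Col1a1 and Cd74 a called and an uncalled probe set are named for the same sequence, where 1 variant could move both. Genes that move together, such as collagens, were also counted as separate trials. The share therefore does not exclude variants. For inherited blocks that carry several changed genes side by side, 2 pairs of adjacent tested genes of unlike name, Pfkp with Akr1c3 and Aldh1l1 with Slc41a3, rose together in the gene order of the GRCr8 assembly, where shuffled orders gave 0.40 pairs on average (3138 genes placed, 10000 permutations, one-sided permutation p = 0.0599). That p gives blocks no support, but the bound set beforehand for excluding them, a p of 0.05 or more, was wrong, since the count lay above the mean of the shuffled orders and a p past 0.05 does not show that blocks are absent.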
